A study of Mus musculus with 14 samples.

How the data were processed

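RNA was sequenced from mouse CD4 T cells that carry an IL-2.eGFP reporter, in which green fluorescent protein (GFP) marks cells transcribing the Il2 locus. The cells came from spleens of C57BL/6 mice. Naive CD4 T cells were activated either in culture or by transfer into mice infected with ActA-LM, the name the labels give to the Listeria strain. Activated cells, which carry the early activation marker CD69, were then sorted into GFP+ and GFP− cells. Per the labels' protocols, the cultured cells received 5 µg/mL anti-CD3, 0.5 µg/mL anti-CD28 and irradiated feeder cells depleted of CD4 cells for 16 to 20 hours, and the transferred cells were recovered after 18 to 24 hours. The series' design text gives 18 to 24 hours for both kinds of activation, so the exact time in culture is open. RNA was extracted with Qiazol and miRNeasy micro kits and libraries were made with the TruSeq Stranded mRNA kit, per the labels' protocols.

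The authors deposited a table of raw read counts for each of 10 libraries, with 34938 RefSeq transcript accessions and 5 summary lines per table. The counts are whole numbers that were not normalized. The submitters' processing notes list Trim Galore 0.4.5, TopHat2 2.0.12, SAMtools 0.1.18, HTSeq 0.7.2, DESeq2 1.18.1 and R 3.4.3 and the genome build GRCm38 (mm10), without saying which step used which setting. The kit marks the strand of origin, but whether reads were counted by strand is not given in the sources used here. The labels also list 4 samples of CD8 T cells activated in culture, which were not analysed here.

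Some features of the counting, read from the deposited counts and their summary lines, bear on the values. Reads were assigned to transcripts, not genes, so that a read shared by several accessions of a gene went into the summary line for ambiguous reads. That line held 30.8 to 32.3% of the reads that fell on annotated exons. A gene with several accessions is therefore undercounted, and 5698 of the 24514 genes (23.2%) have several. Txnip, Myc and Irf7, for example, had no counts in any library, and Gapdh was near 0. In addition, reads with several alignments made up 19.1 to 28.9% of the entries per library and were not assigned, so values of genes with near-identical copies are uncertain. Among the genes named here these are Hspa1a, Hspa1b, Lyz1, Lyz2, Eno1, Ifit1, Ifit3, Gbp2, Gbp10, Tgtp1, Mndal and the Oas and Oasl genes. Finally, 26 of the 204 genes named here have an exon that overlaps an exon of another gene on the opposite strand. For 6 of them, Chaf1a, Cxcr5, Cyp51, Gnl3, Hspe1 and Tcp1, the overlapping gene had a mean level at least 50% as high, and their values are uncertain because strand counting is not stated. For Arl6, Cd247, Csf1r, Cxcl10, Heatr1, Il12rb2 and Tpi1 the overlapping gene was not among the tested genes, so its level was not compared.

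The summary line for reads outside annotated transcripts differed between libraries. It held 40.56% (GFP−) and 40.87% (GFP+) of the entries in the set 1 libraries of cultured cells, 7.5% and 6.35% in their set 2 libraries, 12.9 to 13.0% in the in vivo GFP− libraries and 9.66 to 9.83% in the in vivo GFP+ libraries. The summary lines stayed out of library sizes and tests.

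Counts were summed per gene symbol with pandas 2.3.3 in Python 3.11.15. Of the accessions, 34630 were matched through a RefSeq table of GRCm38.p6 and a further 197 through GENCODE transcript metadata. The other 111 kept their accession as their name. Of these, NR_046233 held the most counts, and the unmatched accessions together held 4.64 to 4.92% of the counts in the in vivo GFP− libraries and 0.5 to 1.26% in the other libraries.

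Libraries were grouped by the labels into in vivo GFP− and GFP+ (sets 1, 2 and 3 each) and in vitro GFP− and GFP+ (sets 1 and 2 each). Replicates were compared before use by a chi-square statistic over transcripts with at least 20 counts in a pair. In vivo sets 1 and 2 differed by about the sampling noise, with 1.07 (GFP−) and 1.05 (GFP+) per degree of freedom, while set 3 differed from set 1 by 2.21 and 2.18 and the in vitro sets differed from each other by 21.65 and 26.31. Sets 1 and 2 in vivo were therefore summed and counted as 1 sample, which leaves 8 libraries, 2 per group, and 4 residual degrees of freedom. This departs from the plan written beforehand, which kept all 10 libraries apart. Nothing in the labels says that sets came from separate mice or cultures, so the p-values measure only the spread between these samples, which may be technical. The common biological coefficient of variation was 3.46% over the in vivo samples and 33.12% over the in vitro samples.

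Gene tests used edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr (10082 genes kept), robust quasi-likelihood fits with a mean per group, quasi-likelihood F tests and Benjamini-Hochberg adjustment over genes, with a threshold of 0.05. All adjusted p-values for genes come from this test unless another is named. The standard error of a log2 fold change was taken as its size divided by the square root of F. The comparisons were GFP+ against GFP− in vivo, the same in vitro, the difference between these differences (the interaction), and all in vivo against all in vitro libraries. The 8 libraries shared a fit so that both ways of activation shared an estimate of the spread. CPM values (counts scaled to a common library total) are TMM-scaled means of the samples of a group, with SD over n = 2.

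Gene lists were written before the data were examined, with Il2 in none of them. Of 21 lists, 19 had enough measured genes for a test. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over the 19 lists within a comparison, and again with an estimated correlation and with fry. The genes named in the text follow a rule also written before the data were examined. It takes a panel of 11 genes, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with a mean CPM of at least 5 and the same direction in every set, and up to 4 members per list with the smallest p. Gene models without an official symbol were skipped for naming, and some genes that the rule names are not reported here. Other members of lists or genes named in the text were chosen after their values were seen. Foxp3 and Il21, both in the panel, had at most 3 counts in any library and were not tested.

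The pipeline was tested on simulated counts with 200 changed genes, drawn from the means and library sizes of the real samples. With a spread shared by the libraries of a set, the in vivo comparison of 9726 genes recovered 55.2% of genes changed by log2 0.5, 76.1% at log2 1 and 90.9% at log2 2, and the in vitro comparison of 9700 genes recovered 52.2%, 64.2% and 86.4%. The interaction, on 9712 genes, recovered 19.4%, 65.7% and 86.4%. None of these runs made a false call. With a spread drawn independently for each library, recovery at the same sizes was 9%, 40.3% and 75.8% in vivo (9676 genes), 19.4%, 56.7% and 68.2% in vitro (9678 genes) and 3%, 25.4% and 62.1% for the interaction (9685 genes). In these runs false calls were 0% of the calls in vivo, 36.8% in vitro, 23.7% for in vivo against in vitro and 13% for the interaction. A list of 27 genes shifted by log2 0.5 was called in every comparison at the preset correlation, and 0 other lists were called. With an estimated correlation and an independent spread, the shifted list was missed in vitro (camera adjusted p = 0.0755) and for the interaction (camera adjusted p = 0.0527).

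Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, other filters on low counts, the set number as a block, fits of only the compared groups, and leaving out each library in turn. The planned fit with all 10 libraries apart was kept as a further alternative. Added after the data were seen were fits with each set left out, without NR_046233 and Lars2, with 1 accession per gene, on transcripts as deposited, and without genes that overlap on the opposite strand. Depth ranged from 1890571 assigned reads (in vivo GFP+ set 2) to 46618172 (in vitro GFP+ set 2). Once in vivo sets 1 and 2 were summed, the samples held 9163315 (in vivo GFP+ sets 1 and 2) to 46596455 (in vitro GFP+ set 2) counts of tested genes. Sequence comparison used blastn 2.17.0, and figures were drawn with matplotlib 3.10.9.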

Results

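RNA was measured in activated CD4 T cells sorted by whether they transcribed Il2. The 10 libraries were in vivo GFP− and GFP+ cells from 3 sets each and in vitro GFP− and GFP+ cells from 2 sets each. Reads assigned to transcripts numbered 8039764, 2007100 and 16569099 in the in vivo GFP− libraries of sets 1, 2 and 3 and 7277893, 1890571 and 15341299 in the GFP+ libraries. In vitro, sets 1 and 2 had 9881652 and 38425864 for GFP− cells and 12409649 and 46618172 for GFP+ cells. In vivo sets 1 and 2 differed by about the sampling noise and were counted as 1 sample, so every group had n = 2. The series title asks whether Il2 expression separates CD4 T cells that will become follicular helper T (Tfh) cells from those that will not, and the comparisons below address how GFP+ and GFP− cells differed soon after activation.

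Il2 itself (NM_008366, chromosome 3, 37120713 to 37125954, GRCm38), the gene the reporter marks, was higher in every GFP+ library than in every GFP− library. Before scaling between libraries, it had 26.7, 31.4 and 31.1 CPM (counts scaled to a common library total) in the in vivo GFP− libraries of sets 1, 2 and 3 and 275, 268 and 261 in the GFP+ libraries. In vitro it had 6.68 and 5.1 in the GFP− libraries and 96.4 and 89.5 in the GFP+ libraries. TMM-scaled CPM rose from 31.1 ± 2.53 to 277 ± 8.74 (SD, n = 2) in vivo, a log2 fold change of 3.15 (SE 0.094, edgeR adjusted p = 1.45e-07). In vitro it rose from 5.55 ± 0.99 to 90.1 ± 4.49, a log2 fold change of 4.08 (SE 0.11, adjusted p = 3.57e-07).

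**Figure D1:**
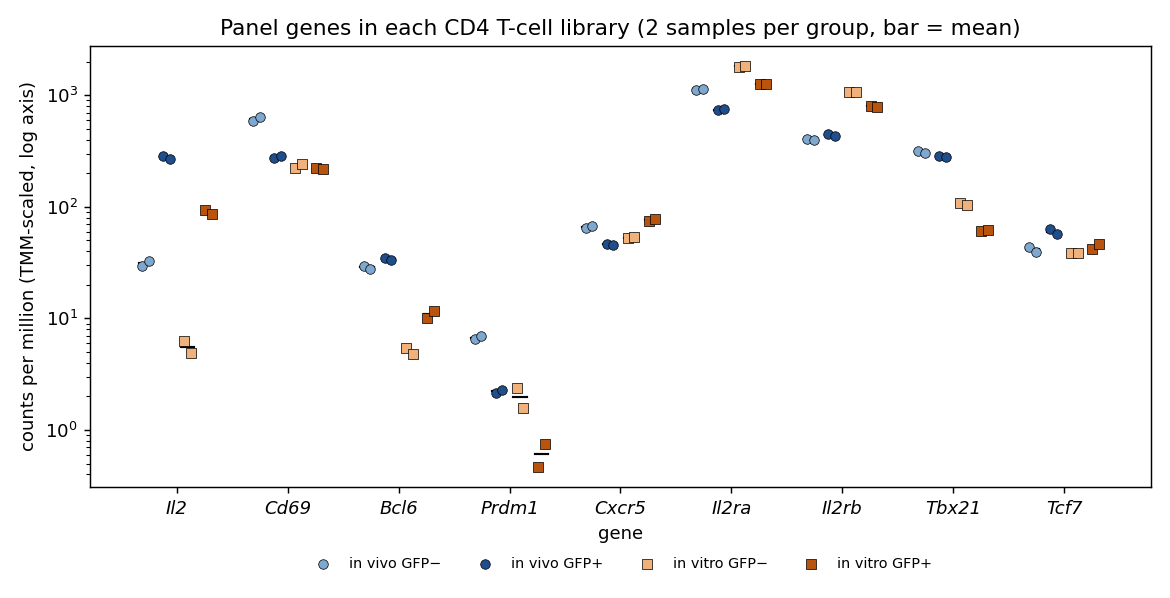
TMM-scaled CPM (log axis) of 9 panel genes in each sample of the 4 groups of CD4 T cells, with 2 samples per group as points and their mean as a bar. Il2 lies at 277 in GFP+ and 31.1 in GFP− cells in vivo and at 90.1 and 5.55 in vitro, and Prdm1 is lower in GFP+ cells in both settings.

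The first comparison asked how GFP+ cells differed from GFP− cells after activation by infection in vivo. GFP+ cells had higher levels of cell-cycle genes and lower levels of interferon-stimulated genes. Genes induced early by the T-cell receptor (TCR) and genes that mark resting T cells were also lower, but these lists did not pass with an estimated correlation between genes (camera adjusted p = 0.112 for each). Prdm1, which encodes Blimp-1, an antagonist of the Tfh regulator Bcl6, fell by 1.6 on the log2 scale (6.74 ± 0.29 CPM in GFP− and 2.22 ± 0.107 in GFP+ cells, SD, n = 2). Its call was lost with either in vivo set left out. Of 10082 genes tested, 3913 passed the threshold, 1986 higher and 1927 lower in GFP+ cells. Of these, 867 differed by at least log2 1, 227 higher and 640 lower. With only genes at a mean CPM of at least 5 tested, 300 did, 44 higher and 256 lower. The direction was the same in every set for 3687 of the 3913 genes (94.2%), with sets 1 and 2 counted apart. The same sets gave the calls, so this is no independent check. With sets 1 and 2 left out 2233 genes passed, and with set 3 left out 2202, where a single sample per group is assumed to vary like the others. With in vitro set 1 or 2 left out of the shared fit, 4778 or 4656 passed.

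Among the panel in vivo, Cd69, the activation marker used for the sort, fell by 1.15 (SE 0.051, edgeR adjusted p = 1.45e-07), from 617 to 279 CPM. Il2ra, the high-affinity chain of the IL-2 receptor, fell by 0.61 (SE 0.03, adjusted p = 2.96e-07) from 1133 to 742 CPM. Cxcr5, the chemokine receptor that guides cells to B-cell follicles, fell by 0.51 (SE 0.06, adjusted p = 0.000119). It overlaps Bcl9l on the opposite strand, which makes its value uncertain. Tcf7, encoding the transcription factor TCF-1, rose by 0.53 (SE 0.083, adjusted p = 0.000761) on the reads that a single accession could claim. Bcl6 had a log2 fold change of 0.24 (SE 0.099, adjusted p = 0.0822) and 28.7 and 33.9 CPM in GFP− and GFP+ cells, and did not pass the threshold. Il2rb, the chain shared with the IL-15 receptor, differed by 0.12 (adjusted p = 0.0235) and Tbx21, the Th1 regulator T-bet, by −0.13 (adjusted p = 0.0266). Both calls were lost with any single in vitro library or either in vivo set left out, that of Il2rb also without the in vivo GFP− library of set 1 or 3 or the GFP+ library of set 1, and that of Tbx21 also without the in vivo GFP+ library of set 3.

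The genes with the largest rises in vivo after Il2 were Mpzl2 (log2 fold change 2.16, SE 0.41, 3.22 to 14.4 CPM), Ehd2 (1.89), Slc9a7 (1.77) and Efnb1 (1.73), which encodes ephrin-B1, a ligand of Eph receptors. Kntc1 (1.61, SE 0.13), a kinetochore protein gene, Prrg4 (1.5), Mapre2 (1.47), Chaf1a (1.40, SE 0.07), a chromatin assembly factor subunit, and Arl6 (1.39) followed. The largest falls were in Lipg (−6.30, SE 0.28, 37.0 to 0.463 CPM), which encodes endothelial lipase, and in the matrix genes Col1a1 (−5.53), Col3a1 (−4.14), Col1a2 (−3.77) and Bgn (−3.44). Dnah8 (−3.75), Oas2 (−3.66), Izumo1r (−3.18, SE 0.12, 67.9 to 7.50 CPM), which encodes folate receptor 4, Ifit3 (−3) and Mndal (−2.82) were next. Col1a1, Mpzl2, Ehd2 and Mapre2 did not pass with either in vivo set left out, Col1a2 did not without set 3, and Mpzl2 and Mapre2 did not pass without the GFP− library of set 3.

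Interferon-stimulated genes were lower in GFP+ cells in vivo. Of 23 measured, 17 fell and 0 rose (18 fell adjusted over the list alone), and the median log2 fold change was −1.12 (camera adjusted p = 5.22e-07, adjusted p = 0.0445 with an estimated correlation). Oas2, Oasl2 and Ifit3, whose products sense or bind viral RNA, fell by 3.66, 2.38 and 3, and Gbp2 fell by 2.38 (245 to 46.6 CPM). TCR-response genes were also lower: 16 of 19 fell and 1 rose, the same when adjusted over the list alone, with a median of −0.41 (camera adjusted p = 5.22e-07, adjusted p = 0.112 with an estimated correlation). Among them were Fosl2 (−2.11), the nuclear receptor genes Nr4a3 (−1.98) and Nr4a1 (−1.61) and the immediate-early gene Egr1 (−1.43), and Dusp4, which encodes a MAP kinase phosphatase, rose by 0.38. Of 12 NF-κB pathway genes, 8 fell (10 adjusted over the list alone, camera adjusted p = 2e-04, adjusted p = 0.0791 with an estimated correlation), among them Icam1 (−0.76), Birc3 (−0.58) and Nfkbia (−0.36).

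Genes of resting T cells were lower in GFP+ cells in vivo, with 9 of 16 measured members falling and 2 rising, over all genes and over the list alone (camera adjusted p = 0.00408, adjusted p = 0.112 with an estimated correlation). Klf2, a transcription factor gene of quiescence and trafficking, fell by 2.49 (63.4 to 11.3 CPM), and the antiproliferative genes Btg1, Btg2 and Tob1 fell by 1.89, 1.46 and 1.1. Cell-cycle genes rose: 14 of 27 rose and 0 fell, the same when adjusted over the list alone, with a median of 0.68 (camera adjusted p = 2.44e-06, adjusted p = 0.0445 with an estimated correlation). The replication licensing genes Mcm2, Mcm3 and Mcm4 rose by 0.71, 0.77 and 0.79 and Top2a, a DNA topoisomerase gene, by 1.04. Ribosome biogenesis genes rose slightly, 11 of 19 rising and 1 falling (12 and 1 adjusted over the list alone, median 0.14, camera adjusted p = 0.00512, adjusted p = 0.193 with an estimated correlation).

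Genes induced by IL-2 through STAT5 went mostly down in vivo: 10 of 17 fell and 4 rose, also when adjusted over the list alone (camera adjusted p = 0.0374, adjusted p = 0.215 with an estimated correlation). Pim1, a kinase gene, fell by 1.01, Socs3, a feedback inhibitor gene, by 1.04 and Il4ra by 0.53, while the survival gene Bcl2 rose by 0.86. Of the 14 measured genes associated with Tfh cells, 2 rose and 5 fell, and the list did not pass (camera adjusted p = 0.632). Cd200 rose by 0.36, and Il6st, Icos and Cxcr5 fell by 0.46, 0.32 and 0.51. Th1-associated genes (3 up, 6 down of 12) and T-cell cytokines (3 up, 7 down of 16) did not pass either (camera adjusted p = 0.262 and 0.381). Among them the cytotoxic protease gene Gzmb fell by 1.26 (202 to 84.1 CPM), Ifng by 1 and Lta by 0.75. Of 11 Treg-associated genes 2 rose and 5 fell (camera adjusted p = 0.21), with Tigit, an inhibitory receptor gene, rising by 1.03 and Izumo1r and Lrrc32 falling by 3.18 and 1.80. The calls on Prdm1 and Ifng were lost with either in vivo set left out.

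Markers of other cells and of the T cells themselves moved with the in vivo groups. The summed level of Col1a1, Col1a2, Col3a1 and Bgn was 95.7 CPM in GFP− and 4.80 in GFP+ cells of the summed sets 1 and 2, and 89.1 and 3.98 in set 3. The B-cell marker list, with only 3 of its 15 members measured, was lower in GFP+ cells (camera adjusted p = 0.0303, adjusted p = 0.178 with an estimated correlation). Spib was at −2.10 and Cd79a at −1.63, both below 3 CPM in every group and both calls lost with either in vivo set left out. The 12 measured myeloid markers summed to 26.9 and 26.0 CPM in sets 1 and 2 and to 25.8 and 30.8 in set 3, and the list did not pass (camera adjusted p = 0.374). Of them 2 were called higher and 0 lower in GFP+ cells. C1qb had 0.0319 and 1.77 CPM and Cd14 0.0846 and 1.21 CPM in GFP− and GFP+ cells. T-cell identity genes were lower in GFP+ cells, 8 of 13 falling and 1 rising (camera adjusted p = 0.00408, adjusted p = 0.138 with an estimated correlation), with Cd3g at −1.08, Thy1 at −0.85 and Cd4 at 0.11. NR_046233 held 4.82, 4.87 and 4.59% of assigned reads in the GFP− and 1.19, 1.2 and 1.14% in the GFP+ libraries of sets 1, 2 and 3, and Lars2, which encodes a mitochondrial leucyl-tRNA synthetase, fell by 2.6 on the log2 scale.

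The second comparison asked the same of cells activated in culture. GFP+ cells again had more cell-cycle and fewer interferon-stimulated transcripts. They also had fewer IL-2-response transcripts, a list that in vivo passed only at the preset correlation, and more Bcl6 and more transcripts of several cytokines. Bcl6 rose by 1.13 (SE 0.11, edgeR adjusted p = 5.4e-05), from 5.07 ± 0.457 to 10.9 ± 1.21 CPM (SD, n = 2). Of 10082 genes, 2354 passed, 1359 higher and 995 lower in GFP+ cells, and 219 differed by at least log2 1, 107 higher and 112 lower. With only genes at a mean CPM of at least 5 tested, 108 passed and differed by at least log2 1, 47 higher and 61 lower. The direction was the same in both sets for 2352 of the 2354, which is close to forced because these sets gave the calls. The sets differed in their share of reads outside annotated transcripts (40.6 and 40.9% against 7.50 and 6.35%), and the log2 fold changes of the sets correlated across genes with r = 0.587. Without the GFP− library of set 1 or 2, 1417 genes (588 higher, 829 lower) or 1448 (899 higher, 549 lower) passed. Without the GFP+ library of set 1 or 2, 1496 (898 higher, 598 lower) or 1269 (558 higher, 711 lower) passed. With set 1 left out 2660 passed (1259 higher, 1401 lower) and with set 2 left out 1510 (785 higher, 725 lower), so whether more called genes were higher or lower depended on the libraries used.

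In vitro, Prdm1 fell by 1.6 (SE 0.31, edgeR adjusted p = 0.00439), from 1.98 to 0.609 CPM. Cxcr5 rose by 0.53 (SE 0.059, adjusted p = 0.000151). Tbx21 fell by 0.79 (SE 0.042, adjusted p = 1.74e-06), Il2ra by 0.51 (SE 0.03, adjusted p = 2.61e-06) and Il2rb by 0.42 (SE 0.033, adjusted p = 1.75e-05). Cd69 at −0.09 (adjusted p = 0.281) and Tcf7 at 0.20 (adjusted p = 0.11) did not pass. After Il2 the largest rises were in Il1r2, the decoy receptor for IL-1 (2.58, SE 0.20, 1.41 to 8.92 CPM), Idi2 (2.19), Pdgfb (1.96), the mitotic kinase gene Pbk (1.90), the chemokine gene Ccl4 (1.84), Cpd (1.82, SE 0.069), Espl1 (1.69), which encodes separase, Gpr25 (1.63) and Myh10 (1.54). The largest falls were in Mir6236 (−2.85), Lars2 (−1.83), Ifit1 (−1.71, SE 0.072), Socs2 (−1.70), Akap12 (−1.6), Zbp1 (−1.59), S1pr1 (−1.53), Dnah8 (−1.5), Gbp10 (−1.46) and Tgtp1 (−1.44). The call on Mir6236 was lost without the in vitro GFP− library of set 2 or either GFP+ library, without either in vivo library of set 3, and with either in vivo set left out. NR_046233 held 0.977 and 1.05% of assigned reads in the GFP− libraries and 0.429 and 0.454% in the GFP+ libraries.

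Of 27 cell-cycle genes, 20 rose in vitro and 0 fell, also when adjusted over the list alone (median 0.71, camera adjusted p = 8.77e-11, adjusted p = 0.0166 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit gene, rose by 1.42, Top2a by 0.96, Rrm1 by 0.70 and Mcm3 by 0.55. Of 23 interferon-stimulated genes, 13 fell and 0 rose (16 fell adjusted over the list alone, median −0.88, camera adjusted p = 1.6e-10, adjusted p = 0.0166 with an estimated correlation), with Gbp2 at −1.39, Irgm1 at −0.88 and Igtp at −0.77. IL-2 and STAT5 response genes fell, 11 of 17 with 0 rising (13 adjusted over the list alone, median −0.51, camera adjusted p = 1.14e-07, adjusted p = 0.0472 with an estimated correlation), among them Socs3 (−0.99) and Pim1 (−0.53). Of 11 Treg-associated genes 7 fell and 0 rose (8 and 1 adjusted over the list alone, camera adjusted p = 0.000282, adjusted p = 0.0472 with an estimated correlation), including Ikzf2 (−0.98), which encodes Helios, and Lrrc32 (−0.95).

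Cytokine genes rose in vitro, 9 of 16 rising and 2 falling (10 and 3 adjusted over the list alone, median 0.82, camera adjusted p = 0.000365, adjusted p = 0.0472 with an estimated correlation). Il3 rose by 2.79 (0.95 to 7.06 CPM), Tnfsf11, which encodes RANKL, by 1.47, Cd40lg by 0.89 and Tnfsf14 by 0.72. Cholesterol synthesis genes rose slightly, 9 of 17 with 0 falling (11 adjusted over the list alone, median 0.25, camera adjusted p = 8.97e-05, adjusted p = 0.0472 with an estimated correlation), with Idi1 at 0.54 and Lss at 0.47. Ribosome biogenesis genes (12 of 19, 15 adjusted over the list alone) and glycolysis genes (8 of 15, 9 adjusted over the list alone) rose with 0 falling (camera adjusted p = 6.83e-06 and 0.00242, adjusted p = 0.0561 for each with an estimated correlation). In these, Utp20 rose by 0.48 and Hk2, a hexokinase gene, by 0.58. Of the 16 quiescence genes 7 fell and 1 rose, also over the list alone (camera adjusted p = 0.00242, adjusted p = 0.0561 with an estimated correlation), with Klf2 at −1.21 and S1pr1 at −1.53.

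Of the Tfh-associated genes, 6 of 14 rose and 5 fell in vitro (7 and 5 adjusted over the list alone, camera adjusted p = 0.41). Bcl6, Cd40lg and Slamf6 rose by 1.13, 0.89 and 0.84 and Icos fell by 0.56. The median of this list was 0.06 and its mean −0.12, which differ in sign. TCR-response genes went both ways, 3 of 19 rising and 8 falling (3 and 9 adjusted over the list alone, camera adjusted p = 0.02, adjusted p = 0.242 with an estimated correlation), with Egr1 at −0.62 and Dusp4 at 0.65. T-cell identity genes (1 up, 5 down of 13) and inhibitory receptors (1 up, 6 down of 13) passed only at the preset correlation (camera adjusted p = 0.0199 and 0.0295, adjusted p = 0.141 and 0.128 with an estimated correlation), and Cd2 fell by 0.79 and Dgka by 0.54. Th1-associated genes (3 up, 4 down of 12) and NF-κB pathway genes (0 up, 4 down of 12) did not pass (camera adjusted p = 0.124 and 0.116), and within the former Cxcr3 rose by 2.84. Myeloid and B-cell markers were near the detection limit in vitro, with Lyz2 at 0.0495 and 0.039 CPM and Cd79a at 1.24 and 0.629 CPM in GFP− and GFP+ cells, and neither list passed (camera adjusted p = 0.41 and 0.157).

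**Figure D2:**
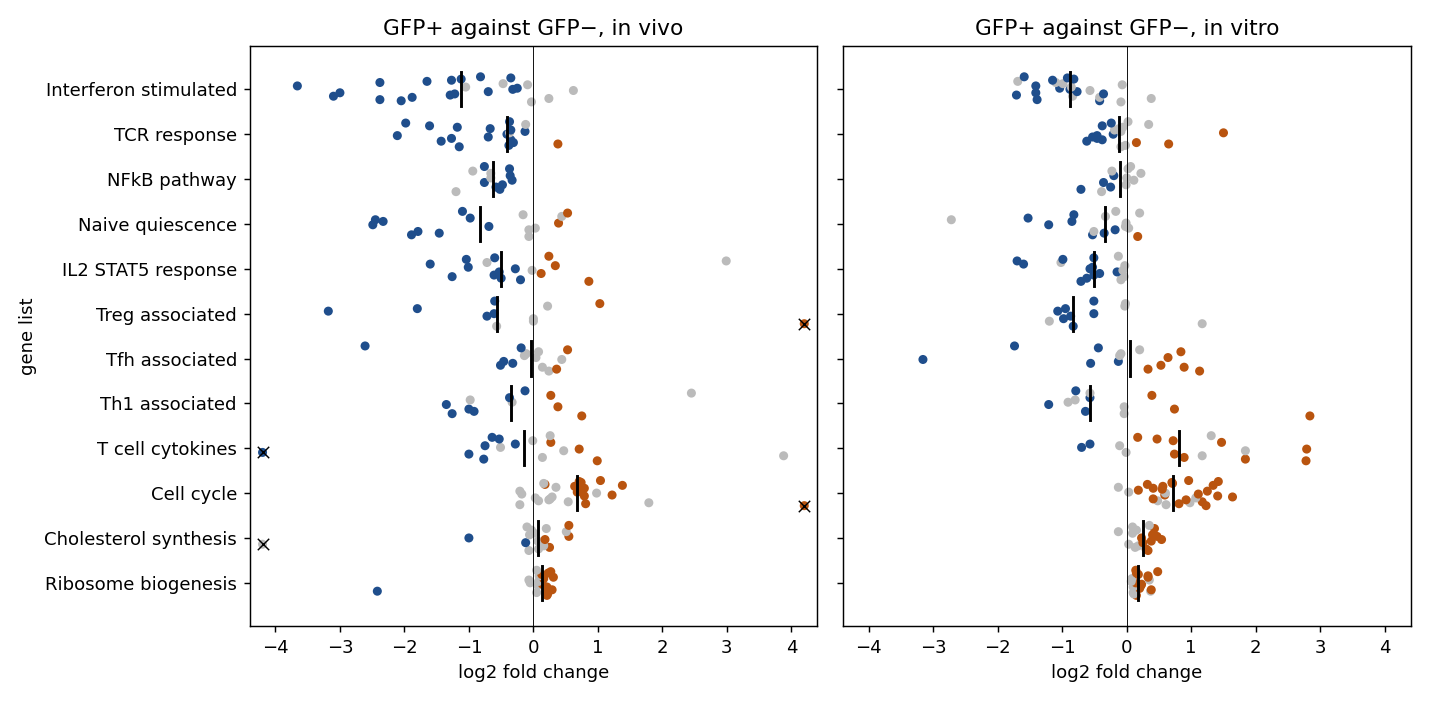
Log2 fold change of GFP+ over GFP− cells for each measured member of 12 gene lists in vivo (left) and in vitro (right); orange and blue points passed the threshold, grey points did not, black bars are medians, and crosses mark members beyond the axis limits (Aurkb, Ebi3, Il13 and Fdps, with a mean below 1 CPM in vivo). Interferon-stimulated genes have a median of −1.12 in vivo and −0.88 in vitro, and cell-cycle genes 0.68 and 0.71.

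Some lists held members with no counts in a whole group. With these members at the bound that 3 counts over the group allow, the median was −0.28 in place of −0.15 for cytokines in vivo, 0.74 in place of 0.82 for cytokines in vitro, 0.70 in place of 0.68 for cell-cycle genes in vivo, −0.52 in place of −0.50 for IL-2 and STAT5 response genes in vivo, and −0.26 in place of −0.37 for inhibitory receptors in vitro. In vivo, the medians of the cholesterol list (0.07) and the heat-shock list (0.06) lie above 0 and their means (−0.18 and −0.27) below 0, and those of the myeloid list are −0.05 and 0.60.

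The third comparison tested whether the reporter difference itself differed between the settings. Across the 10082 genes, the in vivo and in vitro log2 fold changes correlated with Pearson r = 0.28 and Spearman rho = 0.403 (genes are not independent replicates). Pearson r was 0.563 over the 6819 genes with a mean CPM of at least 5 and 0.068 over 15704 genes with no filter on low counts. Of the called genes, 848 were higher in GFP+ cells in both settings (267.7 would be shared by independent lists) and 690 were lower in both (190.2). Opposite calls were made for 31 genes higher in vivo and lower in vitro (196 by chance) and 74 lower in vivo and higher in vitro (259.7). The interaction passed for 1254 genes, 436 with a higher and 818 with a lower log2 fold change in vivo (34.8% higher), and 566 and 686 (45.2% higher) with upper-quartile scaling. With the in vivo sets 1 and 2 left out 598 genes passed, with set 3 left out 512, with in vitro set 1 or 2 left out 1620 or 950, and without single libraries 675 to 1229.

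**Figure D3:**
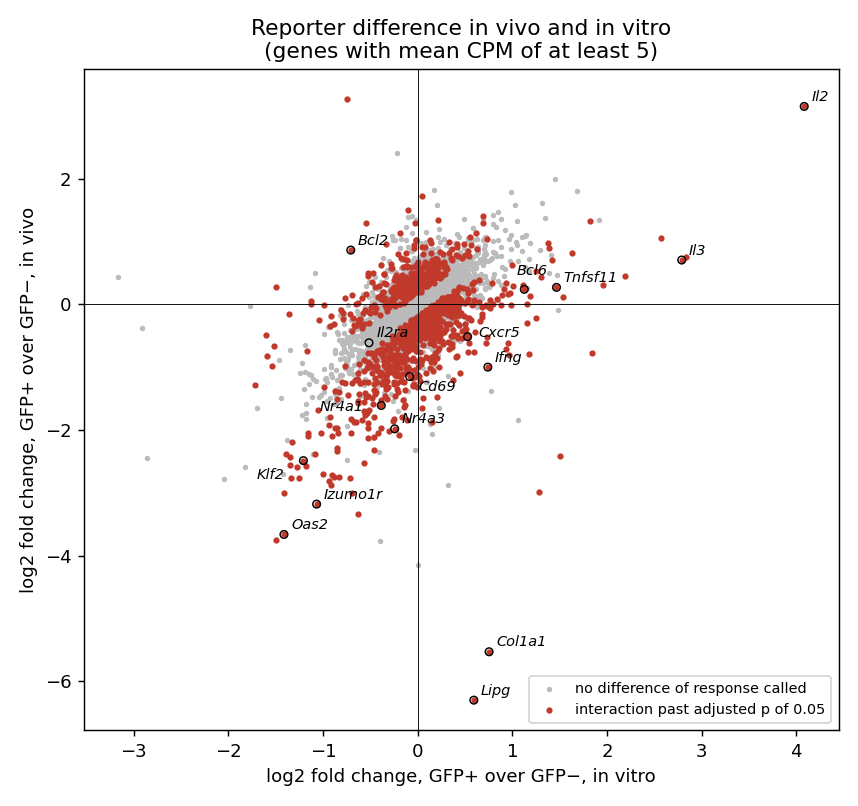
Log2 fold change of GFP+ over GFP− cells in vitro (x axis) and in vivo (y axis) for genes with a mean CPM of at least 5, with the genes past the interaction threshold in red. Il2 lies at 4.08 in vitro and 3.15 in vivo, while Cd69 lies at −0.09 and −1.15 and Bcl6 at 1.13 and 0.24.

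Immediate-early and activation genes had lower log2 fold changes in vivo than in vitro. Of 19 TCR-response genes 13 had a lower log2 fold change in vivo and 0 a higher one (14 adjusted over the list alone, median difference −0.47, camera adjusted p = 4.35e-08, adjusted p = 0.165 with an estimated correlation). The differences were −1.74 for Nr4a3 (SE 0.058), −1.65 for Fosl2, −1.22 for Nr4a1 and −1.06 for Cd69 (SE 0.071, edgeR adjusted p = 1.68e-05). Of 16 cytokine genes 11 were lower (11 lower and 1 higher adjusted over the list alone, median −1.03, camera adjusted p = 1.12e-05, adjusted p = 0.123 with an estimated correlation), with Ccl4 at −2.61, Tnfsf11 at −1.2, Tnfsf8 at −0.81 and Lta at −0.64. NF-κB pathway genes (4 of 12 lower, 5 adjusted over the list alone, median −0.45, camera adjusted p = 0.0118) and cholesterol synthesis genes (5 of 17 lower, 8 adjusted over the list alone, median −0.23 or −0.21 with members at their bound, camera adjusted p = 0.0168) also passed (adjusted p = 0.165 for each with an estimated correlation). Nfkb1 differed by −0.44 and Insig1, a regulator of sterol synthesis, by −1.23. Interferon-stimulated genes went both ways, 5 higher and 5 lower of 23 (camera adjusted p = 0.413), with Ddx58 at −1.64 and Irgm1 at 0.57.

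In the panel, the interaction was −0.93 for Il2 (SE 0.14, edgeR adjusted p = 0.00436), −0.89 for Bcl6 (SE 0.15, adjusted p = 0.0037), −1.04 for Cxcr5 (SE 0.085, adjusted p = 5.11e-05), 0.54 for Il2rb (SE 0.048, adjusted p = 9.82e-05) and 0.65 for Tbx21 (SE 0.059, adjusted p = 0.000101). It did not pass for Il2ra (−0.10, adjusted p = 0.177) or Tcf7 (0.32, adjusted p = 0.102), and Prdm1 differed by 0.00. The Il2 and Bcl6 interactions did not pass with either in vivo set left out, and that of Bcl6 also not without in vitro set 2. The largest positive interactions were in Pla2g4f, which had 0.0637 and 0.824 CPM in GFP− and GFP+ cells in vivo and 25.7 and 15.4 in vitro, and in Ccdc141 (1.85), Syp (1.77), Efnb1 (1.68), Prrg4 (1.6), Bcl2 (1.57, SE 0.089), Plekhm3 (1.33), Prickle1 (1.29), Tbkbp1 (1.22) and Ptprf (1.14). Bcl2 had 43.1 and 78.4 CPM in GFP− and GFP+ cells in vivo and 219 and 134 in vitro. The largest negative ones were in Lipg (−6.89), Col1a1 (−6.28), Adh1 (−4.27), Ifitm3 (−3.91, SE 0.15), Slc25a45 (−2.70), Ccl4 (−2.61), Tbc1d30 (−2.31), Dnah8 (−2.25), Oas2 (−2.25) and Izumo1r (−2.11, SE 0.16). Those of Col1a1 and Oas2 did not pass with either in vivo set left out, and that of Col1a1 was also lost without any of 4 single libraries (in vivo GFP− set 3, in vivo GFP+ set 1 or 3, in vitro GFP+ set 2) and without in vitro set 2. Those of Efnb1 and Plekhm3 did not pass without the in vivo GFP− library of set 1, that of Efnb1 not without in vivo sets 1 and 2, and those of Plekhm3, Ccdc141 and Tbc1d30 not without in vivo set 3.

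The last comparison set all in vivo against all in vitro libraries and describes the ways of activation. Interferon-stimulated genes were higher in vivo, 17 of 23 with 3 lower, over all genes and over the list alone (median 2.32, camera adjusted p = 1.58e-05, adjusted p = 0.043 with an estimated correlation). Rsad2 had 63.6 and 20.2 CPM in GFP− and GFP+ cells in vivo and 0.313 and 0.0806 in vitro, a log2 difference of 7.82 (SE 0.123), and Usp18, an interferon-induced protease gene, differed by 4.55. All 17 measured cholesterol synthesis genes were lower in vivo, also over the list alone (median −1.78, camera adjusted p = 1.25e-07, adjusted p = 0.043 with an estimated correlation), with Cyp51 at −2.56 and Idi1 at −2.50. Cell-cycle genes were lower in vivo, 23 of 27 with 1 higher (camera adjusted p = 1.79e-05, adjusted p = 0.043 with an estimated correlation), with Top2a at −2.51 and Cdk1 at −2.54. Th1-associated genes were higher, 10 of 12 with 2 lower (camera adjusted p = 0.000994, adjusted p = 0.0727 with an estimated correlation), with Gzmb at 4.49 and Tbx21 at 1.88. Ribosome biogenesis genes were higher (17 of 19, camera adjusted p = 1.76e-05, adjusted p = 0.0899 with an estimated correlation), and Bcl6 was higher by 2.07 and Prdm1 by 1.80. In all, 7437 genes differed, 3508 higher and 3929 lower in vivo.

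The largest differences between the settings lay among genes close to the detection limit in a setting. Higher in vivo were the heat-shock genes Hspa1a (10.61, 118 and 95.5 CPM in GFP− and GFP+ cells) and Hspa1b (8.73), Maf (10.08), Lyz2 (8.43, 15.2 and 15.0 CPM), Cxcl10 (8.05), Plac8 (8.04), Rsad2 (7.82) and Map1b (7.39). Gpnmb had 20.5 and 15.8 CPM in GFP− and GFP+ cells in vivo and 0.0597 and 0 in vitro, and Col3a1 had 0 counts in every in vitro library. Lower in vivo were Ccl22 (0.0846 and 0.0338 CPM in GFP− and GFP+ cells in vivo, 13.0 and 9.3 in vitro), Selp (−7.26), Eno1 (−7.23), Xist (−6.97), Lrrc32 (−6.54), Akr1c18 (−6.36), Pla2g4f (−6.24), Tcp1 (−6.11) and Myo6 (−6.10). All 12 measured myeloid markers were higher in vivo (camera adjusted p = 1.79e-05, adjusted p = 0.0703 with an estimated correlation). Xist, transcribed from the inactive X chromosome of female cells, had 2.42 ± 1.56 CPM in vivo and 247 ± 17.1 in vitro (SD, n = 4), and the Y-linked genes Ddx3y, Eif2s3y and Kdm5d had 141, 87.2 and 56.9 CPM in vivo and 68.2, 63.4 and 34.4 in vitro. Sex-linked transcripts thus differed along with the way of activation, and the labels do not say what a set number stands for, so activation and sex of the cells cannot be told apart in this comparison. Eno1 also differed between the in vitro sets, with 70.7 and 29.6 CPM in the GFP− libraries of sets 1 and 2, and its call was lost without in vivo set 3.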

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

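The tests of the interferon and TCR genes against signalling without antigen and against myeloid cells were chosen after the results were seen. The interaction was tested gene by gene with edgeR, and its results are given because the GFP+ to GFP− difference differed between activation in vivo and in vitro.

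The interaction passed for 1254 genes. The log2 fold change was lower in vivo by −0.93 for Il2, −1.06 for Cd69, −0.89 for Bcl6 and −1.04 for Cxcr5, and higher by 0.54 for Il2rb and 0.65 for Tbx21. The median differences of the lists that passed were −0.47 for TCR-response genes, −1.03 for cytokines, −0.23 for cholesterol synthesis genes and −0.45 for NF-κB pathway genes (camera adjusted p = 0.123 for cytokines and 0.165 for each of the others with an estimated correlation). Sex-linked transcripts differed between the settings along with the way of activation. A shift shared by the GFP+ and GFP− cells of a setting cancels in the interaction, but one that alters the reporter difference does not. The interaction therefore cannot be credited to the activation alone.

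Reads outside annotated transcripts made up 40.56% (GFP−) and 40.87% (GFP+) of the entries of the in vitro set 1 libraries, a signal outside the gene comparisons, and these sets also differed at a minority of genes. Genes with an opposite-strand partner at least 10 times higher were 0.86 (median log2) higher in set 1 than in set 2, against 0 for genes with no overlap, in the GFP− pair (interval 0.69 to 1.12) and by 0.86 in the GFP+ pair (0.58 to 1.12). These genes were picked by their set 2 level against that of the partner, and a low set 2 level by itself pushes this ratio up. The shift of at least 1 set beforehand lies inside the intervals. The test therefore cannot decide whether set 1 holds reads of both strands, and that explanation stays open. Low genes without such overlap were 0.62 (GFP−) and 0.64 (GFP+) higher relative to the others. They too were picked by a low set 2 level, which raises the ratio whatever the cause. Reads from unspliced RNA or genomic DNA in set 1 thus stay open as well. Ambiguous reads were 10.79% (GFP−) and 11.08% (GFP+) of the entries in set 1, against 22.1% and 22.58% in set 2. Their share of the reads on annotated exons stayed close, at 31.97% and 31.64% against 32.34% and 32.0%. Reads of both strands counted by strand would lower the former and not the latter, but so could added reads outside exons. These values thus do not decide between the explanations. No biological explanation was tested, since nothing in the labels separates the sets.

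NR_046233 and Lars2 were higher in GFP− cells in both settings. The in vivo count of called genes moved little without both, 3684 against 3913. Leaving out these features does not test whether the GFP− and GFP+ libraries differ in what their share reflects. Reads with several alignments also differed in vivo, at 27.8 to 28.9% of entries in GFP− and 19.1 to 20.5% in GFP+ libraries. A Lars2 transcript aligned over 0 bases to any of the 356 ribosomal transcripts of the reference. The bound set beforehand for excluding shared sequence was not a fair one, because the longest transcript searched has 1849 bases and the large nuclear ribosomal RNA is not among them, so reads shared with ribosomal RNA stay open. A difference between GFP+ and GFP− cells themselves is likewise open and untested.

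Interferon-stimulated and TCR-response genes were both lower in GFP+ cells in vivo (camera adjusted p = 0.0445 and 0.112 with an estimated correlation). The summed myeloid markers moved by −0.05 in sets 1 and 2 and by 0.25 in set 3, and of 12 members 2 were called higher and 0 lower in GFP+ cells. These values give no sign of more myeloid RNA in the GFP− sort. They do not exclude it, because Lyz2, whose value is uncertain, made up most of the sum (15.2 and 15.0 CPM in GFP− and GFP+ cells). Stromal RNA stays open: the sum of 20 stromal genes without the called collagens had log2 ratios of −1.33 and −1.43 (12.6 to 5.02 and 10.7 to 3.98 CPM). Highest in GFP− cells were Col4a2, Col5a1, Col5a2 and Fbln1 (1.63 to 2.72 CPM), while Mgp was higher in GFP+ cells. Dcn, Sparc, Col4a1, Col6a3, Pdgfra, Pdgfrb, Igfbp7 and Postn had 0 CPM in every in vivo sample. The 0 CPM of Dcn and Sparc decides nothing, because both have several accessions. Nothing ties the interferon genes to such cells. Cells activated by interferon without antigen signalling in the GFP− sort would go with lower TCR-response genes there. Of 19 such genes, 16 were higher and 1 was lower in GFP− cells, which argues against these cells as the source of the TCR part of the pattern. Whether they contribute to the interferon part stays open, since the median of −0.41 of the TCR-response genes is part of the pattern and no test of it. A later or different stage of activation in the GFP− cells may contribute and was not tested.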

How the results depend on the processing

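The main fit, with in vivo sets 1 and 2 summed, was chosen after the replicates were compared. The planned fit with all 10 libraries apart called 3860 genes in vivo, 1812 in vitro, 1054 for the interaction and 7240 between settings. DESeq2 called 2973 genes in vivo, 2078 in vitro and 970 for the interaction, and limma-voom 3430, 3189 and 1126. The main fit called 3913, 2354 and 1254. By at least log2 1, 605, 159 and 156 of the DESeq2 calls differed, against 867, 219 and 306 in the main fit. The fits with whole sets left out, without NR_046233 and Lars2, with 1 accession per gene, on transcripts and without opposite-strand overlaps were chosen after the data were seen. With in vivo sets 1 and 2 left out, 2233 genes passed in vivo and 598 for the interaction; with set 3 left out, 2202 and 512. With in vitro set 1 left out 2660 passed in vitro, 1620 for the interaction and 4778 in vivo, and with in vitro set 2 left out 1510, 950 and 4656. Leaving out single libraries gave 1269 to 2345 genes in vitro and 675 to 1229 for the interaction, where a lone sample is assumed to vary like the others. Fewer samples enter these fits. The correlation of 0.28 between in vivo and in vitro log2 fold changes became 0.383 over genes called in either, 0.337 with limma-voom, 0.068 with no filter on low counts, 0.563 at a mean CPM of at least 5, 0.208 and 0.228 without in vivo sets 1 and 2 or set 3, 0.217 and 0.2 without in vitro set 1 or 2, 0.326 with 1 accession per gene and 0.101 to 0.285 without single libraries. The cause was not tested.

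The main fit does not pair samples by set number. In vivo, deviations of same-numbered samples correlated across genes with r = 0.06, 0.06 and 0.28 for sets 1, 2 and 3. In vitro, where there are only 2 pairs, r was 0.94, so the GFP− and GFP+ libraries of a set deviated together. The main in vitro and interaction tests do not model this shared deviation. With the set number as a block, 5507 genes passed in vivo, 4988 in vitro and 3574 for the interaction. Between settings 7355 of 9965 genes passed, in a fit that also kept all 10 libraries apart. Some lists that camera called at the preset correlation did not pass with the block. These were IL-2 and STAT5 response genes and B-cell markers in vivo (camera adjusted p = 0.0657 for each), T-cell identity genes in vitro (0.0523) and cholesterol synthesis genes for the interaction (0.0725). On simulated counts with a spread shared by set, 3.3, 11.6 and 5.2% of the calls of the block fit in vivo, in vitro and for the interaction were false, against 0 without the block, and with an independent spread 0, 25.6 and 6.7%, against 0, 36.8 and 13%. The cause was not tested.

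The fry test called more lists than camera, and in vivo it called every list. Tfh-associated genes, which camera did not call, were called lower in GFP+ cells in vivo (fry adjusted p = 0.00458). For the same list fry gave a higher level in vitro (fry adjusted p = 0.000925) and a lower interaction (fry adjusted p = 0.00115). In 3 lists that camera did not call, the direction called by fry was opposite to that of camera. They were cholesterol genes in vivo (fry adjusted p = 0.026), heat-shock genes in vivo (0.0178) and inhibitory receptors for the interaction (0.0058). For inhibitory receptors between settings the directions also differed, but neither test called the list (fry adjusted p = 0.795). Tyrobp, in vitro, had counts in a single library, and its fitted value depends on the prior count: the log2 fold change was 0 without in vitro GFP− replicate 2, which is that library, or with set 2 left out, and −4.75 without GFP− replicate 1. Over all alternatives, 9286 values of named genes kept direction and side of the threshold, 255 lost a call, 42 gained one and 2 changed direction. Foxp3 and Il21, with at most 3 counts in any library, could not be tested at this depth and with this counting.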

Other observations

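The splits of the samples were chosen after the results were seen. Members of the inhibitory receptor list went both ways in vivo (2 up, 5 down of 13, camera adjusted p = 0.328), for the interaction (2 up, 4 down, adjusted p = 0.979) and between settings (6 higher, 7 lower in vivo, adjusted p = 0.987). Tigit was higher in GFP+ cells in vivo (63.6 to 130 CPM) and had a log2 fold change of −0.02 in vitro, an interaction of 1.04 that was lost without in vitro set 2. Lag3 rose by 0.19 in vivo and fell by 0.37 in vitro. Pdcd1, which encodes PD-1, rose by 0.64 in vitro and had 0.04 in vivo. Dgka, a diacylglycerol kinase gene that limits TCR signalling, fell by 1.73 in vivo, from 181 to 54.4 CPM.

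Of 11 heat-shock and stress genes, 4 rose and 3 fell in vivo (camera adjusted p = 0.861) and 6 rose and 1 fell in vitro (adjusted p = 0.124). The chaperone gene Hspd1 rose by 0.30 in vivo and 0.46 in vitro, while Atf3 fell by 2.31 and Ddit4 by 0.99 in vivo. Glycolysis genes rose for 5 of 15 in vivo with 0 falling (adjusted p = 0.0587). Of 4 CD8 and NK markers 2 fell in vivo (adjusted p = 0.374) and 1 rose in vitro (adjusted p = 0.936), and Cd8b1 had 70.2 and 51.5 CPM in GFP− and GFP+ cells in vivo and 35.7 and 41.7 in vitro, although the sort was for CD4 cells. Between settings, Treg-associated genes were lower in vivo (8 of 11, adjusted p = 0.00975, adjusted p = 0.0899 with an estimated correlation), as were IL-2 and STAT5 response genes (14 of 17, adjusted p = 0.00328, adjusted p = 0.0999 with an estimated correlation), while Tfh-associated genes were higher (10 of 14, adjusted p = 0.0209, adjusted p = 0.114 with an estimated correlation).

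Splits of the samples were counted for the comparisons with at least 3 libraries per group. Between in vivo and in vitro libraries 5599 genes passed in the fit used for splits, the most of 35 splits, and the highest other gave 2. Taken over libraries as if they were independent, 1 of 35 splits gave as many, a share under 0.05. The libraries of an in vitro set deviated together, however, and with whole sets as the units the splits are too few for such a share. The splits therefore do not exclude chance. For GFP+ against GFP− in vivo with all 6 libraries apart, 4419 genes passed and the highest other split gave 0; 1 of the 10 splits gave as many, and 10 splits are too few for a share under 0.05.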
